A study of Mus musculus with 10 samples.

How the data were processed

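Gene expression was measured on 10 Affymetrix MoGene 2.0 ST arrays, each hybridised with amplified RNA of mouse intestinal cells. Per the labels' protocols, single cells were prepared and sorted by flow cytometry, RNA was extracted with the miRNeasy Micro kit, and it was amplified and labelled with the Ovation Pico WTA V2 and Encore Biotin kits. The gates of the sort are not given in the sources used here. Of the arrays, 6 came from cells sorted for high Lgr5 and GFP (Lgr5-high) and 4 from crypt cells labelled as expressing Flattop, the product of Cfap126. All mice were 3 to 6 months old, per the labels.

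The deposited values are log2 intensities per probe set. Per the submitters' processing notes, the authors used robust multi-array averaging (RMA) in the R package oligo 1.38.0, which corrects background, normalises arrays and summarises probes. The order of steps and any later filter are not given in the sources used here. Scanner files were not used here, so the log2 scale rests on these notes and on the range of the values, 2.01 to 14.1, with none missing. Values were not centred per gene. Array medians lay between 4.56 and 4.77. Neither detection calls nor signal over background could be set beside the values, and the number of arrays limits the precision.

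The table held 41345 probe sets. In the platform annotation, 23521 had 1 gene symbol, 1814 had several and 16010 were not listed, which leaves them unnamed here. Names were checked through Entrez gene numbers against the RefSeq genes of assembly GRCm38.p6, where 23328 probe sets matched and 0 symbols changed. Each of the 22180 genes was represented by its probe set of highest mean over the arrays, and 1082 genes had more than 1 probe set. No filter on dim probe sets was applied. Alpha-defensin (Defa), lysozyme and Reg genes have near-identical relatives, so probes may detect several of them and their values are uncertain as to which copy was measured.

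Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, Flattop minus Lgr5-high, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The 34 gene lists, covering epithelial lineages, pathways, cell cycle, other cell types, dissociation, strain, sex and gut region, were compared with other genes by limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were alternatives. The groups, the tests of genes and lists, the 34 lists and the alternatives were fixed before the data were examined, apart from 2 alternatives named as later additions. The interaction of group and title number range, the further gene lists and the tests of explanations in the closing section were added afterwards, some of them after the result was seen. Named genes were Lgr5 and Cfap126, up to 12 genes with the largest rise and 12 with the largest fall among genes past the threshold whose groups did not overlap, up to 4 members of each list with the smallest p, and members of the lists of other cell types, quality, strain, sex and region as needed. Predicted, small RNA, olfactory, vomeronasal, immunoglobulin and T cell receptor genes were left out of the largest changes. A gene named outside this rule is said to have been chosen after its values were seen.

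The method was tested on simulated data with the means and spreads of these 22180 genes and 200 genes changed by known amounts. It recovered 44.8% of genes changed by 1 on the log2 scale, 86.6% of those changed by 2 and 98.5% of those changed by 4. Of 160 calls, 7 were false (4.38%). The simulated noise was independent between genes, with 1 spread per gene for both groups. In the data, genes of a list were correlated (estimated at 0.745 for the lymphocyte list). Spreads could also differ between groups, as for Cd3g (SD 1.03 in Flattop and 0.19 in Lgr5-high). The simulated rates may therefore not hold for the calls made here.

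Alternatives were a second quantile normalisation, centring of each array on its median, removal of genes under the 40th percentile of mean intensity, a trended and robust variance prior, array weights, a block for replicate number, a block for the range of the numbers in the sample titles (1 to 8 or 38 to 46), each range alone, each array left out in turn, all probe sets, the mean of a gene's probe sets, a threshold of 0.1 and a 2-fold minimum. Chosen after seeing the data were a block for sex, read from Xist, and the removal of the least correlated array of each group. The labels do not say whether title numbers mark batches. Plots were drawn with matplotlib 3.10.9.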

Results

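The data compared crypt cells labelled as expressing Flattop, a protein linked to planar cell polarity and cilia, with intestinal stem cells sorted for high Lgr5. The question was how expression in Flattop-expressing cells, which the study links to a Wnt/planar cell polarity state and to the enteroendocrine and Paneth lineages, departs from that of Lgr5-high stem cells. There were 4 Flattop and 6 Lgr5-high arrays. The Flattop cells came from mice with a Cre inserted at the Flattop gene and a membrane colour reporter at ROSA26, on a mixed background that includes C57BL/6J and CD1, and the Lgr5-high cells came from C57BL/6J mice with an EGFP and CreERT2 insertion at Lgr5. Group, genotype and strain therefore coincide and cannot be told apart. Nothing in the labels says that replicates came from separate animals, so p-values measure only the spread between these samples, which may be partly technical. Xist was high in 3 of 4 Flattop and 2 of 6 Lgr5-high arrays, so the arrays of a group did not all come from animals of the same sex. Pearson correlations across all probe sets were 0.869 to 0.941 within Flattop, 0.854 to 0.915 within Lgr5-high and 0.825 to 0.931 between groups. No pair of arrays was identical. Lgr5-high replicate 1 correlated most with Flattop replicate 2 (r = 0.931).

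Lgr5 (Entrez gene 14160), the receptor that marks crypt base stem cells, had a mean log2 intensity of 8.37 ± 1.42 (SD, n = 4) in Flattop and 9.47 ± 0.33 (SD, n = 6) in Lgr5-high arrays. The difference of -1.10 (SE 0.51) did not pass the limma test (adjusted p = 0.533), and a second Lgr5 probe set gave -0.65. The 4 Flattop arrays read 9.19, 9.65, 6.44 and 8.21 for Lgr5. Cfap126 (Entrez gene 75472), which encodes Flattop, was at 5.42 ± 0.74 (SD, n = 4) against 4.996 ± 0.349 (SD, n = 6), and its difference of 0.43 (SE 0.31) did not pass either (adjusted p = 0.678). The 4 Flattop arrays read 4.67, 4.93, 6.20 and 5.89 for Cfap126, and the difference was -0.44 within titles 1 to 8 and 1.29 within titles 38 to 46. Where the inserted cassettes lie relative to the probes of these genes was not examined.

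Genes of differentiated epithelial lineages and of lymphocytes were higher in the Flattop arrays, and few genes were lower. Fabp6, the ileal bile acid binding protein, rose by 7.10 on the log2 scale (SE 0.63, adjusted p = 0.000328), from 5.15 ± 1.39 (SD, n = 6) to 12.25 ± 0.34 (SD, n = 4). The chemokine Ccl5 rose by 6.99 (SE 0.28). The T cell receptor component Cd3g rose from 3.67 ± 0.19 to 10.10 ± 1.03, the granzymes Gzma from 4.36 ± 0.45 to 10.28 ± 1.04 and Gzmb from 4.03 ± 0.22 to 9.04 ± 1.23, and the protease Mcpt1 from 3.31 ± 0.37 to 8.38 ± 0.19 (SD, n = 6 and 4). Without detection calls the size and the order of these 4 differences are uncertain, since their Lgr5-high means lay under the median of all values (4.70), that of Mcpt1 also under the lower quartile of every array (3.59 to 3.84). The goblet cell lectin Zg16 rose by 5.70 (SE 1.07, adjusted p = 0.0354). Xcl1 (5.43), Cd7 (5.38), Cd3e (5.30), Clec2h (4.99) and Reg1 (4.97) also rose. The Lgr5-high means of Cd3e (4.73), Xcl1 (4.87), Clec2h (4.93), Cd7 (5.14) and Fabp6 (5.15) lay little above 4.70. The size and order of their differences are therefore uncertain too. Reg1 missed the threshold without Flattop replicate 2 (adjusted p = 0.0515). The genes that fell were the dynein heavy chain Dnah8 (-1.44, SE 0.24), the membrane mucin Muc4 (-0.77, SE 0.14) and the histone mRNA binding protein Slbp (-0.75, SE 0.15), with adjusted p of 0.0187, 0.0349 and 0.0468. Dnah8 missed the threshold without Flattop replicate 1 (adjusted p = 0.0525) and without Flattop replicate 4 (adjusted p = 0.0631).

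Of 22180 genes, 203 passed an adjusted p of 0.05 in limma, 200 higher and 3 lower in Flattop, and 186 of the 200 were at least 2-fold higher. At an unadjusted p under 0.05 there were 1326 higher and 843 lower genes, against 1109 in all by chance. The groups did not overlap in 661 genes (2.98%, against 0.952% by chance), among them 201 of the 203. With the title number range as a block 220 genes passed, within titles 1 to 8 (2 Flattop, 3 Lgr5-high) 77 did, and within titles 38 to 46 (2 and 3) 85 did, 10 of them lower. A second quantile normalisation gave 162 higher and 16 lower genes. Without Flattop replicate 2 the count was 123 (5 lower), without Lgr5-high replicate 4 it was 132, and without Lgr5-high replicate 1 the lower genes numbered 1. Zg16 missed the threshold when any array other than Lgr5-high replicates 5 and 6 was left out (adjusted p 0.0542 to 0.102). Muc4 did so for any array other than Flattop replicate 4 (0.0504 to 0.0862) and Slbp for any other than Flattop replicate 1 (0.0722 to 0.131).

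**Figure D1:**
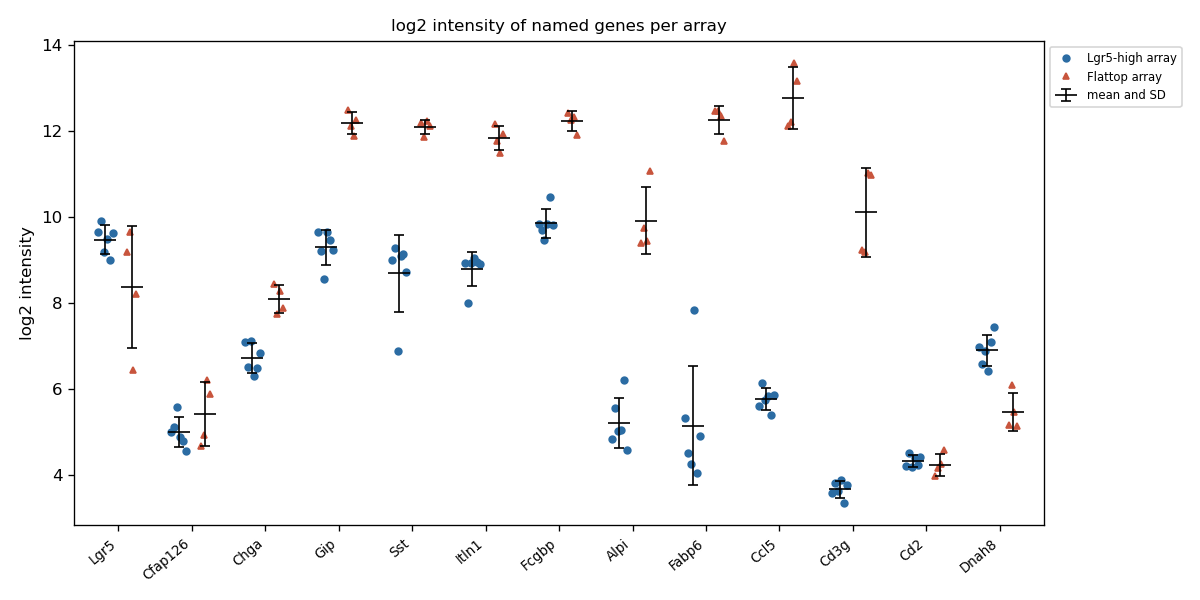
log2 intensity (vertical axis) of 13 named genes (horizontal axis) in each Lgr5-high array (circles) and Flattop array (triangles), with group means and SD in black. Ccl5 averages 12.76 in Flattop and 5.77 in Lgr5-high arrays and Cd3g 10.10 and 3.67, whereas Cd2 differs by -0.09 and the Lgr5 values of the groups overlap.

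Lymphocyte genes rose in the Flattop arrays. Of 11 measured genes of the T cell and intraepithelial lymphocyte list, 10 rose over all genes tested and 10 adjusted over the list alone, with a median difference of 4.91. The list mean was 9.27 ± 1.05 (SD, n = 4) in Flattop and 4.71 ± 0.16 (SD, n = 6) in Lgr5-high arrays. Cd8a rose by 3.89, the pan-leukocyte phosphatase Ptprc by 4.91 and the integrin Itgae, which tethers lymphocytes to epithelium, by 4.35 (2.79 with adjusted p = 0.0614 within titles 1 to 8). Cd2 was the exception at -0.09 (adjusted p = 0.853). In Lgr5-high arrays 5 of the 11 genes lay above the median of all values (4.70). Camera gave an adjusted p of 1.86e-33, and the call held with adjusted p = 0.0123 with an estimated correlation. The median was 3.78 within titles 1 to 8 and 5.93 within titles 38 to 46, and that of dissociation response genes was -0.40 and 0.79.

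Paneth and antimicrobial genes were higher in the Flattop arrays too. Of 17 measured Paneth cell genes, 8 rose over all genes and 13 adjusted over the list alone (median 3.04, camera adjusted p = 1.41e-22, and adjusted p = 0.0077 with an estimated correlation). The lectin Itln1 rose by 3.04 (SE 0.22), Clps by 3.72, Mptx2 by 4.94 and the alpha-defensin Defa26 by 3.19, the last uncertain as to the copy measured. Of the 5 antimicrobial Reg genes, 3 rose over all genes and 5 adjusted over the list alone (median 3.49, adjusted p = 4.83e-13, and adjusted p = 0.0077 with an estimated correlation). Reg4, also counted with enteroendocrine genes, rose by 3.47 and Reg3a by 2.15, while Reg3g differed by 3.95 (adjusted p = 0.0650). It passed without Lgr5-high replicates 5 or 6 (0.0446 and 0.0495), with dim probe sets left out (0.0398) and with a trended and robust prior (0.0440). The lymphocyte list was higher by 4.91 in the same Flattop arrays.

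Hormone genes rose, whereas enteroendocrine transcription factors did not pass. Of 30 enteroendocrine hormone and granule genes, 7 rose over all genes and 12 adjusted over the list alone (median 0.66, camera adjusted p = 7.23e-18, and adjusted p = 0.0077 with an estimated correlation). The incretin Gip rose by 2.89 (SE 0.22), somatostatin (Sst) by 3.40 (SE 0.41) and chromogranin A (Chga) by 1.36 (SE 0.21). The 18 measured transcription factors had a median of 0.04 and none passed over all genes or adjusted over the list alone (limma; 1 higher and 2 lower at an unadjusted p under 0.05, camera adjusted p = 0.825, mean -0.16). Neurog3, the factor that starts this lineage, was at -1.66 (SE 0.74, limma adjusted p = 0.501). It was at 0.21 within titles 1 to 8 and at -3.53 within titles 38 to 46 (adjusted p = 0.0377). Sox4 was at -1.16 (limma adjusted p = 0.481), -0.13 within titles 1 to 8 and -2.19 within titles 38 to 46. A second Sox4 probe set gave -0.52. Flattop replicate 3 read 6.645 for Sox4, where the other Flattop arrays lay between 8.80 and 9.755. Chga missed the threshold without the least correlated array of each group (adjusted p = 0.0699) and within either title range (0.379 and 0.121). The list median was 0.43 without Flattop replicate 1 and 1.08 without Flattop replicate 3, 1.22 within titles 1 to 8 and 0.41 within titles 38 to 46, 1.08 with dim probe sets left out and 1.03 without the least correlated array of each group. These hormone differences were measured beside the lymphocyte difference of 4.91.

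Goblet and enterocyte genes also rose. Of 16 goblet cell genes, 8 rose over all genes and 14 adjusted over the list alone (median 1.24, camera adjusted p = 2.60e-25, and adjusted p = 0.00961 with an estimated correlation), among them the mucus protein Fcgbp (2.37), Clca1 (2.74) and the chemokine Ccl6 (4.10). Of 22 enterocyte genes, 10 rose over all genes and 20 adjusted over the list alone (median 1.83, camera adjusted p = 3.66e-36, and adjusted p = 0.0077 with an estimated correlation). Intestinal alkaline phosphatase Alpi rose by 4.69 (SE 0.38), sucrase-isomaltase Sis by 4.72 (SE 0.43) and the apolipoproteins Apoa1 and Apoa4 by 2.70 and 3.29. Both lists were higher in the same group as the lymphocyte list (4.91). In Flattop replicates 1 to 4 the lymphocyte list means were 8.13, 8.69, 10.44 and 9.81. The goblet means were 10.45, 10.27, 9.46 and 9.72, and the enterocyte means 8.77, 9.10, 8.31 and 9.56. Across these arrays the goblet means ran in the reverse order of the lymphocyte means, and the enterocyte means in neither order. So few arrays do not show whether the lists vary independently. The tuft cell list was not called (median 0.17, adjusted p = 0.428), with 0 of 20 genes past the threshold over all genes and 0 adjusted over the list alone. Nor was the secretory progenitor list (median 0.14, adjusted p = 0.194), with 0 of 10 and 1. Within titles 1 to 8 both lists passed as higher (adjusted p = 0.0282 and 0.0292, medians 0.254 and 0.206). Within titles 38 to 46 neither list passed, and their medians were -0.096 and 0.022. At an unadjusted limma p under 0.05 1 tuft cell gene was higher, and 4 secretory progenitor genes were higher and 2 lower.

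**Figure D2:**
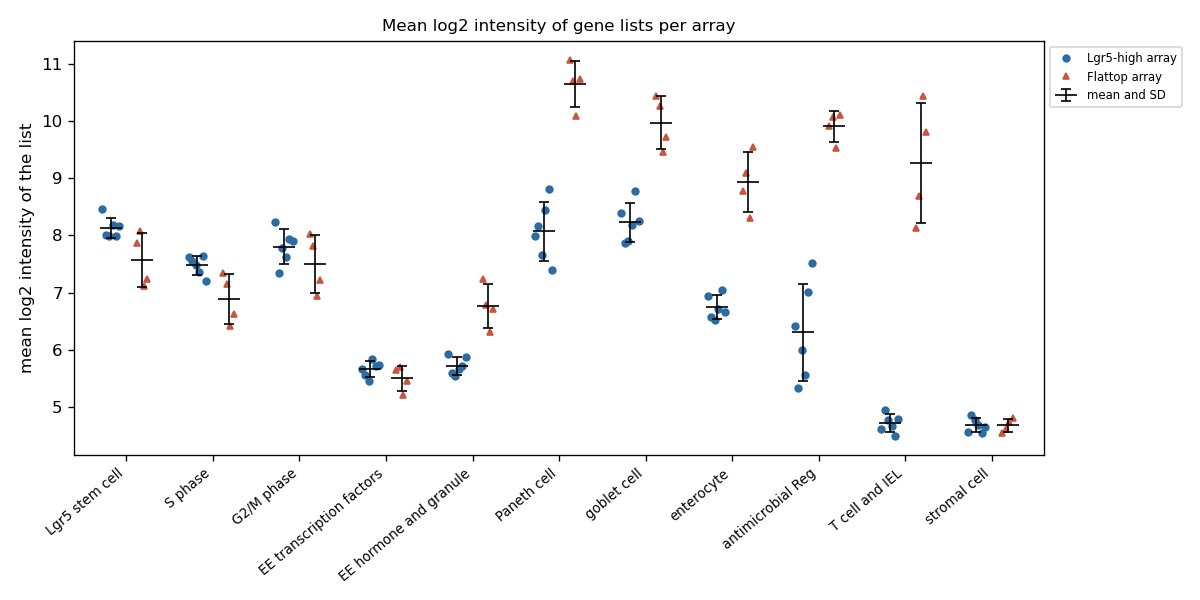
Mean log2 intensity (vertical axis) of the measured genes of 11 lists (horizontal axis; EE, enteroendocrine; IEL, intraepithelial lymphocyte) in each Lgr5-high array (circles) and Flattop array (triangles), with group means and SD in black. The lymphocyte list averages 9.27 in Flattop and 4.71 in Lgr5-high arrays, and the stem cell list 7.57 and 8.13.

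Stem cell and cell cycle lists were lower in the Flattop arrays by camera's preset correlation, and these calls were lost when the correlation was estimated. All 27 measured Lgr5 stem cell genes had negative differences (median -0.49), 0 passed over all genes in limma, 6 were lower adjusted over the list alone and 11 at an unadjusted p under 0.05 (camera adjusted p = 2.09e-07, and adjusted p = 0.237 with an estimated correlation). Gkn3 was at -1.17 (adjusted p = 0.114) and Rgmb at -1.06 (adjusted p = 0.124, 0.0179 with the title number block and 0.0281 after a second quantile normalisation). Of 20 S phase genes, 1 fell, Slbp, also the 1 adjusted over the list alone, while all 20 differences were negative and 9 genes were lower at an unadjusted p under 0.05 (median -0.62, adjusted p = 2.09e-07, and adjusted p = 0.199 with an estimated correlation). Of 24 G2/M genes, 0 passed over all genes or adjusted over the list alone and 3 were lower at an unadjusted p under 0.05 (median -0.35, adjusted p = 0.0285, and adjusted p = 0.534 with an estimated correlation), and the median was 0.026 within titles 1 to 8, -0.78 within titles 38 to 46 and -0.58 with the sex block. The S phase median was -0.37 within titles 1 to 8. The stem cell median was -0.16 within titles 1 to 8 (adjusted p = 0.134) and -0.84 within titles 38 to 46. In the same 2 ranges the lymphocyte median was 3.78 and 5.93 and the dissociation median -0.40 and 0.79. The dissociation change lay largely in the Lgr5-high arrays, with list means of 7.36, 8.03 and 7.89 in replicates 1 to 3. Those of Lgr5-high replicates 4 to 6 were 6.84, 6.63 and 7.42, and those of Flattop replicates 1 to 4 were 7.63, 7.28, 7.39 and 8.16. Flattop replicates 3 and 4 had stem cell list means of 7.11 and 7.24 and lymphocyte list means of 10.44 and 9.81, against 7.87 and 8.07 and 8.13 and 8.69 in replicates 1 and 2. The G2/M call ended without Flattop replicate 3 (adjusted p = 0.383, median -0.15), without Flattop replicate 4 (0.167) and without Lgr5-high replicates 1 or 5 (0.221 and 0.0793), each left out alone, with array weights (0.0571) and without the least correlated array of each group (0.0615).

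Endoplasmic reticulum folding and glycolysis lists were higher by camera's preset correlation. Of 23 endoplasmic reticulum folding genes, 3 rose over all genes and 11 adjusted over the list alone (median 0.53, adjusted p = 6.29e-10, and adjusted p = 0.0916 with an estimated correlation). They were the stress sensor Ern2 (1.74) and the cochaperones Dnajb11 (0.78) and Dnajc3 (1.25), which passed in 8, 1 and 6 of 21 alternatives. Within titles 38 to 46 the list median was 0.32 and Ern2 was at 0.89 (adjusted p = 0.408). Ern2 missed the threshold without any array other than Flattop replicates 3 and 4 (adjusted p 0.0683 to 0.135), Dnajb11 without any other than Lgr5-high replicate 5 (0.0792 to 0.139) and Dnajc3 without any other than replicate 4 of either group (0.0735 to 0.117). Of 12 glycolysis genes, 1 rose, Pfkp by 2.33, also the 1 adjusted over the list alone (median 0.25, adjusted p = 0.000234, and adjusted p = 0.0916 with an estimated correlation). Pfkp missed the threshold without Flattop replicate 4 (0.0568) and without Lgr5-high replicates 4 or 6 (0.0525 and 0.0510). Among 7 cyclin-dependent kinase inhibitors, 0 passed over all genes and 2 were higher adjusted over the list alone (median 0.05, mean 0.36, adjusted p = 0.0349, and adjusted p = 0.280 with an estimated correlation). That call ended without Flattop replicate 1 (adjusted p = 0.196, median -0.14) and without Lgr5-high replicate 4 (0.0537), after a second quantile normalisation (0.143) and with dim probe sets left out (0.137). Its median lay between 0.03 and 0.25 when any array other than Flattop replicate 1 was left out. The oxidative phosphorylation list was not called (median 0.05, adjusted p = 0.298), with 0 of 20 genes past limma's threshold over all genes, adjusted over the list alone or unadjusted, but it passed without Flattop replicate 3 (adjusted p = 0.00877) and without the least correlated array of each group (0.0189). Within titles 38 to 46 the glycolysis and kinase inhibitor calls ended (0.115 and 0.177, medians 0.14 and 0.14), the latter also within titles 1 to 8 (0.0890, median 0.23). The glycolysis median was 0.39 within titles 1 to 8 and 0.17 after a second quantile normalisation, and the kinase inhibitor median was 0.013 after that normalisation, 0.17 with array weights, 0.0057 with the sex block and 0.24 without the least correlated array of each group.

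Wnt and polarity lists were not called over all arrays. None of 42 Wnt/planar cell polarity genes passed limma over all genes or adjusted over the list alone, and 4 were lower at an unadjusted p under 0.05 (median -0.08, camera adjusted p = 0.656), although fry, which does not compare the list with other genes, gave an adjusted p of 0.0442 toward lower values. The smallest p-values of the list were those of Celsr2 (-0.29, adjusted p = 0.431) and Wnt11 (-0.40, adjusted p = 0.457). Medians were -0.16 for canonical Wnt targets (adjusted p = 0.0673), 0.04 for the Notch pathway (adjusted p = 0.568), -0.09 for motile cilium genes (adjusted p = 0.341) and -0.16 for reserve stem cell genes (adjusted p = 0.178, and 0.0368 toward lower values by fry). In these 4 lists 0 genes passed over all genes or adjusted over the list alone, and at an unadjusted limma p under 0.05 2 canonical Wnt target genes and 1 reserve stem cell gene were lower, 1 Notch gene was higher and 1 lower, and 0 cilium genes differed. The canonical Wnt list passed as lower without Flattop replicates 1 or 2 (adjusted p = 0.0129 and 0.00632) and without Lgr5-high replicate 6 (0.0375). It also passed as lower with the title number block (0.0425), with the sex block (0.0242), after a second quantile normalisation (0.00888), with dim probe sets left out (0.0179) and within titles 38 to 46 (0.00264), but not within titles 1 to 8 (median -0.04).

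Markers of other cell types divided. Of 12 myeloid genes, 2 rose over all genes and 3 adjusted over the list alone (median 0.06, mean 0.70, adjusted p = 0.0413, and adjusted p = 0.287 with an estimated correlation). They included the signalling adaptors Tyrobp (3.98) and Fcer1g (3.62), which lymphocytes with natural killer receptors also use, while the macrophage gene Csf1r was at -0.09. The myeloid call ended without Flattop replicates 3 or 4 (adjusted p = 0.0653 and 0.0688) and without Lgr5-high replicates 1, 3 or 5 (0.178, 0.0641 and 0.0511), as well as within either title range (0.125 and 0.115), with array weights (0.0567) and without the least correlated array of each group (0.0615). The myeloid median was 0.0069, 0.09, 0.012 and 0.10 without Lgr5-high replicates 1, 2, 3 and 6 and 0.012 without Flattop replicate 2, -0.035 and 0.024 within titles 1 to 8 and 38 to 46, 0.11 after a second quantile normalisation and 1.75 with dim probe sets left out. Endothelial genes were lower by camera (median -0.24, 0 of 8 past the threshold and 1 lower adjusted over the list alone, adjusted p = 0.0254, and adjusted p = 0.281 with an estimated correlation), a call that ended without Flattop replicates 1 or 2 (0.0606 and 0.0636) and without Lgr5-high replicate 2 (0.0513), with the sex block (0.0588) and within titles 38 to 46 (0.635). The endothelial median was -0.15 without Flattop replicate 2, -0.38 within titles 1 to 8 and -0.067 within titles 38 to 46. The endothelial list averaged 4.24 in Flattop and 4.47 in Lgr5-high arrays, both under the median of all values (4.70). Its call therefore concerns genes of low intensity. Medians were -0.10 for B and plasma cells, -0.11 for stroma, 0.05 for the 1 measured erythroid gene and -0.06 for glia, none called (adjusted p = 0.652, 0.702, 0.709 and 0.825). In these 4 lists 0 genes passed limma over all genes or adjusted over the list alone, and at an unadjusted p under 0.05 there were 1 higher B cell gene and 1 higher and 1 lower stromal gene. The glial list had a negative median and mean but was placed on the higher side by camera.

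Among the region, stress and background lists, the distal and proximal lists were called over all arrays. Fabp6 was the 1 distal gene of 6 to rise, also the 1 adjusted over the list alone (median 0.11, adjusted p = 0.0349, and adjusted p = 0.227 with an estimated correlation). The distal call ended without Flattop replicates 1 or 3 (0.0644 and 0.0646) and without Lgr5-high replicates 1 or 5 (0.0742 and 0.0869), and without the least correlated array of each group (0.0736). The distal median was 0.011 and 0.17 without Flattop replicates 3 and 4, 0.070 without Lgr5-high replicate 1, 0.025 without the least correlated arrays, 0.19 after a second quantile normalisation and 3.86 with dim probe sets left out. Of 7 proximal genes 0 passed over all genes and 2 were higher adjusted over the list alone (median 0.44, adjusted p = 0.0371, and adjusted p = 0.287 with an estimated correlation), and this call ended without Flattop replicates 1 or 4 (0.128 and 0.108) and without Lgr5-high replicate 2 (0.0591), with the sex block (0.344), after a second quantile normalisation (0.159) and with dim probe sets left out (0.123). Within titles 38 to 46 neither was called (0.195 and 0.319), and the proximal median was 0.09 there and 0.28 without Flattop replicate 2. The dissociation list had a median of 0.24 (adjusted p = 0.0688), interferon response 0.03 (adjusted p = 0.126, 1 higher adjusted over the list alone), MHC class II -0.44 with all 6 genes negative (adjusted p = 0.0688), strain-dependent genes 0.17 (adjusted p = 0.209) and sex-linked genes -1.01 (adjusted p = 0.557). In these 5 lists 0 genes passed limma over all genes, 0 others passed adjusted over the list alone, and at an unadjusted p under 0.05 there were 2 dissociation genes, 2 strain-dependent genes and 4 interferon genes that were higher and 1 interferon and 1 MHC class II gene that were lower. The dissociation list passed as higher without Flattop replicate 2 (adjusted p = 0.0168) and without Lgr5-high replicates 2 or 3 (0.00736 and 0.0178). Its median was 0.79 within titles 38 to 46 (adjusted p = 0.000106) and -0.40 within titles 1 to 8, where it was not called. The strain-dependent list passed by camera with dim probe sets left out (median 0.86, adjusted p = 0.0286) and within titles 1 to 8 (0.46, 0.0282). Within titles 38 to 46 its median was -0.12. MHC class II passed as lower in 6 of 21 alternatives, among them without Flattop replicate 3 (0.0369) and without Lgr5-high replicates 2 or 3 (0.0353 and 0.0254). Xist, expressed from the inactive X chromosome of females, was at 11.32 or above in 3 Flattop and 2 Lgr5-high arrays and at 5.18 or below in the others. Of the 34 lists, camera called 12 higher and 4 lower, and 6 and 0 with an estimated correlation. Fry called 14, without the G2/M, kinase inhibitor, myeloid and proximal lists (adjusted p = 0.320, 0.109, 0.0918 and 0.195).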

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

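Tests chosen only after the result was seen were those of general epithelial purity, array scaling, mature secretory cells, the number range and stem cell content. For 140 combinations of a named gene and a group, the array farthest from its group was compared with the group's range, and 7 stood apart, where chance gives about 1 in 20.

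Lymphocyte genes were higher by a median of 4.91 in the Flattop arrays. Loss of epithelial purity in general would raise genes of other cell types too. All 45 B cell, stromal, endothelial, myeloid, erythroid and glial genes had a median of -0.094 (95% interval over genes -0.165 to 0.047, 17 positive). Intervals over genes treat the genes of a list as independent and leave out the spread between arrays. As a set these 45 genes did not rise, but most lay under the median of all values. The 14 whose mean lay above it had a median of -0.028 (95% interval over genes -0.15 to 0.96). Of these, 2 passed the threshold, Tyrobp and Fcer1g, which lymphocytes with natural killer receptors also use. The interval of the 14 is too wide to decide. Unequal sexes are argued against by the list median of 5.17 with a sex block. RNA from intraepithelial lymphocytes in the sort may account for the pattern. The 32 further lymphocyte genes, none from the fixed lists, had a median of 1.36 (interval over genes 0.96 to 2.27). Of these, 31 had positive differences, 8 of them past the threshold. Genes of the lymphocyte list were correlated (estimated at 0.745), and if these are too, their interval is too narrow. In Lgr5-high arrays 14 of the 32 already lay above the median of all values. Ccl5 reached 12.76 and Gzma 10.28 in Flattop arrays, and whether the gates would remove such cells is not given in the sources used here, so expression by the cells labelled as expressing Flattop, whose Cfap126 did not pass the test (0.43, limma adjusted p = 0.678), strain and genotype stay open.

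Genes of enterocytes, goblet, Paneth and enteroendocrine cells were higher together in the Flattop arrays. Scaling of the arrays was examined by centring and a second quantile normalisation. Under both, the 4 lists stayed past the threshold with a lowest median of 0.62 (hormone and granule genes, 95% interval over genes 0.28 to 1.18). The deposited values were already normalised, and the median difference over all genes only moved from -0.064 to -0.044 and -0.041. Neither step could therefore move the lists far, so this test does not decide. Unequal sexes are argued against by the sex block, under which 4 of 4 lists kept a median over 0.5 (0.58 to 2.92) and passed the threshold. Mature secretory cells rather than their progenitors are a candidate explanation: the score of hormone and granule genes minus that of transcription factors was higher by 1.21 in Flattop arrays (exact permutation p = 0.00476, two-sided, n = 4 and 6, the smallest these groups can give). This contrast was chosen after the list values were seen, so it leaves the question open. A further state of differentiation in the sorted cells, the sort, strain and genotype stay open. Cfap126 did not pass the limma test, but this does not test the Flattop label. That label came from a Cre and a reporter, and whether it follows the Cfap126 level of the sorted cells was not examined.

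Lgr5 read 6.44 and 8.21 in the Flattop arrays numbered 38 and 42, and 9.19 and 9.65 in those numbered 4 and 8. A number range that shifts all arrays alike would give an interaction of group and range near 0. It was -1.88 (95% interval -3.40 to -0.36, limma adjusted p = 0.160 over 191 named genes), which does not decide, as Lgr5 was examined because of these values. Fewer stem cells in these 2 samples could lower the other stem cell genes alike, and their median interaction was -0.54 (interval over genes -1.18 to -0.16; list adjusted p = 3.44e-07 by camera, and adjusted p = 0.163 with an estimated correlation). The shift was not particular to stem cells, since 15 of 34 lists had such an interaction at the preset correlation and 0 with an estimated one. Among the 15 were lymphocyte (1.81), dissociation (1.10), goblet (-0.77) and G2/M (-0.71) genes. The dissociation change lay largely in the Lgr5-high arrays, whereas the stem cell and lymphocyte changes lay in the Flattop arrays. The cause of the Lgr5 values stays open.

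For 5 of the 191 named genes the interaction of group and number range passed when adjusted over those 191. Many of these genes were named for their values in these same data, so this adjustment is not independent of them. Over all 22180 genes 2 passed, none of them among the 5, and 1639 had an unadjusted p under 0.05, against 1109 by chance. The difference between groups was larger within titles 38 to 46 than within titles 1 to 8 by 1.81 for Cd3g, by 2.74 for Cd3e and by 3.13 for Itgae (limma adjusted p = 0.0182 for each over 191 named genes, and 0.212, 0.212 and 0.218 over all genes). For Cfap126 it was larger by 1.73, at -0.44 within titles 1 to 8 and 1.29 within titles 38 to 46 (adjusted p = 0.0216 over the named genes and 0.244 over all genes). For the Notch pathway gene Dtx1 it was larger by 1.66, at 0.17 within titles 1 to 8 and 1.83 within titles 38 to 46 (adjusted p = 0.0356 over the named genes and 0.333 over all genes).

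Fabp6 was at 11.75 in Flattop replicate 4, where the other Flattop arrays lay between 12.34 and 12.45. Fabp6 was also at 7.83 in Lgr5-high replicate 4, above the 4.06 to 5.32 of the others. Itln1 was at 7.99 in Lgr5-high replicate 2, below the 8.91 to 9.05 of the others. Sst was at 6.88 in Lgr5-high replicate 3, below 8.73 to 9.28. Clca1 was at 8.60 in Lgr5-high replicate 6, below 9.61 to 9.83. Fgf15 was at 4.41 in Flattop replicate 4, below 4.88 to 4.96. Xist was at 5.01 in Flattop replicate 3, where the other Flattop arrays lay between 11.32 and 11.74. That value belongs with the low Xist readings from which sex was read.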

How the results depend on the processing

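All 53 named genes past the threshold kept their direction in each of 1112 combinations of gene and alternative, and 918 of these passed. The 16 called lists kept their direction by the list test in 367 of 368, and 309 passed. The exception was the G2/M list, whose median was 0.026 within titles 1 to 8 (adjusted p = 0.389); the cause was not tested. Medians took the sign opposite to the list test for cyclin-dependent kinase inhibitors without Flattop replicate 1 (-0.14) and for myeloid genes within titles 1 to 8 (-0.035). Of 155 named genes not past the threshold, 10 passed in some alternative. The sex block and the removal of the least correlated arrays were chosen after seeing the data; they gave 161 and 175 genes.

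Against 203 genes (200 higher, 3 lower), leaving out each array in turn gave 123 to 215 genes, 118 to 211 higher and 1 to 5 lower. Within titles 1 to 8 there were 77 (77 higher, 0 lower) and 2 lower lists, and within titles 38 to 46 there were 85 (75 higher, 10 lower), with fewer arrays. An adjusted p of 0.1 gave 311 genes, 19 lower. Lower genes numbered 16 after a second quantile normalisation, 6 with the title number block, 6 over all probe sets and 1 at a 2-fold minimum; the cause was not tested. Camera with an estimated correlation called 6 lists, 6 higher and 0 lower, against 16, since correlated members widen its error. Without each array in turn, 13 to 17 lists were called.

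Replicate numbers do not pair the samples: deviations of arrays with the same number correlated at 0.297, -0.206, -0.010 and 0.029. With a replicate block 57 genes passed, 57 higher and 0 lower, and 54 were among the 203. Under that block 14 lists were called, and the canonical Wnt list passed as lower (adjusted p = 0.0373). Signal over background was not used here, so how far low intensities limit the calls is open.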

Other observations

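Tests chosen only after the result was seen were those of bile acid responsive genes and of lower genes alone near the modified loci. Several further genes past the threshold were chosen after their values were seen. The transporter Slc51a was higher by 3.67, the keratin Krt20 by 4.48 and the retinol binding protein Rbp2 by 4.15, with limma adjusted p of 0.000519, 0.00247 and 0.00262. All are members of the enterocyte list and already counted in its result, so they add no separate evidence. Gimap4 (3.77), Ptpn22 (3.99) and Cd96 (4.01), genes of lymphocytes, were higher in the same arrays, with limma adjusted p of 0.00313, 0.00297 and 0.0198. Cd96 missed the threshold without Flattop replicate 4 (0.0577) and without Lgr5-high replicate 3 (0.0521), and was at 2.47 within titles 1 to 8 (0.0956).

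The count of 203 genes was set beside other groupings of these arrays. In all, 100 splits of the 10 arrays into 4 and 6 were drawn from 210, with the real one included. Of these, 1 called as many genes, and the highest of the others called 4. An arbitrary split of these arrays would thus rarely give such a count. The splits treat arrays as independent, which the labels do not show, so sources shared by the arrays of a group are not excluded.

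Cd2 was at -0.09 while other T cell genes rose. Lymphocytes low in conventional T cell genes might give this. The 10 such genes, 1 of them also in the fixed lists, had a median of -0.016 (95% interval over genes -0.25 to 0.98). In limma 0 of them passed the threshold. The members divide: Cd5 was at -0.02 and Cd28 at -0.25, whereas Thy1 was at 0.98 (adjusted p = 0.598) and Il7r at 1.54 (adjusted p = 0.0890, and 0.0370 without Flattop replicate 4). Cd5 and Cd28 averaged 4.86 and 4.04 in Flattop arrays, near the median of all values (4.70), so this stays open.

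Mcpt1 rose from 3.31 to 8.38. Mast cells in the sort might raise other mast cell genes, whose median over 9 genes was -0.00208 (95% interval over genes -0.03 to 1.002). Of the 9, 2 rose, Mcpt2 (3.22) and Kit (1.002), and the others lay between -0.11 and the 0.34 of Cpa3 (adjusted p = 0.569). Kit missed the threshold without Flattop replicates 2, 3 or 4 (adjusted p = 0.0781, 0.0507 and 0.0619), each left out alone. These values do not decide, and mast cells cannot be told apart from other sources.

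Fabp6 rose by 7.10. Bile acid responsive genes might rise with it, but their median over 7 genes was 0.00825 (95% interval over genes -0.21 to 3.67). Slc51a was at 3.67 and Fgf15 at -0.06 (limma adjusted p = 0.916). The value of Slc51a had been seen before, so this stays open.

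Strain backgrounds differ between the groups, and genes linked to the 3 modified loci might differ for that reason. Around Cfap126, among the 100 nearest tested genes in the order of assembly GRCm38.p6, 18 had an unadjusted p under 0.05, a share that 0.98% of 10000 random windows reached, against 22.4% for Lgr5 and 64.0% for Gt(ROSA)26Sor. The window holds Slamf7 (2.19), Fcer1g (3.62) and Itln1 (3.04), of the lymphocyte and Paneth patterns. Further leukocyte genes among the 18, chosen after their values were seen, were not past the adjusted threshold. Cd244a (2.62), Cd48 (2.05), Sh2d1b1 (1.33), Ly9 (0.999) and Cd84 (0.35) were higher, and Slamf8 (-0.41) and Fcrlb (-0.27) lower. The window also holds Pea15a (1.58, limma adjusted p = 0.0198), which is in none of the lists and was chosen after its value was seen. Pea15a missed the threshold without Flattop replicates 2 or 4 (0.0693 and 0.0688) and without Lgr5-high replicate 6 (0.0509), each left out alone. Slamf7 (adjusted p = 0.0361) missed the threshold without any array other than Flattop replicates 1 and 3 (0.0675 to 0.110), and was at 1.30 within titles 1 to 8 (0.289). Lower genes alone numbered 4, a share that 35.0% of random windows reached, so linkage and other sources of these differences cannot be told apart here.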
